A study of Caenorhabditis elegans with 4 samples.

How the data were processed

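Chromatin from embryos of a worm strain carrying GEI-11 fused to GFP and FLAG tags was analysed in 2 ChIP samples, and input DNA was sequenced as the control in 2 samples. Per the labels' protocols, worms were grown at 20 °C, crosslinked with 2% formaldehyde and quenched with 100 mM Tris, chromatin was sonicated, 10% of the lysate was kept as input, and the rest was precipitated with anti-GFP antibodies. Groups and replicate numbers came from the sample titles. The input samples entered no comparison of their own: their reads were not analysed here.

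The deposited values are peak lists. Per the file headers, positions are on genome build WormBase WS220, and the source field of each record names SPP, a ChIP-seq peak caller, followed by IDR, a procedure that keeps peaks whose rank is reproducible between replicates. Each record holds a position, a peak number and a score, which is the authors' own value for that peak. The scale of the score is not named in the files, so it was used only to rank peaks within a list. The aligner, the tool versions, the thresholds, how input was used and how the combined list was derived are not given in the sources used here. The replicate lists hold the same number of peaks (30000), so their lengths say nothing about the yield of a library, and their weaker peaks extend to very low scores. Read depth is unknown, and intervals on shares of peaks cover counting error only.

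Peaks were ranked by score, with ties ordered by the peak number in the list. In the combined list 856 of 1539 peaks shared the highest score, as did 1154 in replicate 1 and 681 in replicate 2, so the order among the strongest peaks rests on that number. The replicate lists were compared at equal depth, using as many top peaks as the combined list holds (1539). Of those, 22 in replicate 1 and 21 in replicate 2 lay on mitochondrial DNA and were left out of the tests, leaving 1517 and 1518. Peaks counted as shared when they overlapped by at least 1 bp. The combined list repeats 7 intervals exactly, and each entry was counted as deposited; merging within 1 kb was an alternative.

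Overlap was tested against 10000 circular shifts of one list within chromosomes (1000 at other depths), domain shares against 10000 shifts on chromosome IV, and gaps against 10000 uniform placements. Counts per chromosome and per part of a chromosome were tested with exact two-sided binomial tests, a chi-square test and Fisher's exact test, with exact Clopper-Pearson 95% intervals and Benjamini-Hochberg adjustment over the 6 chromosomes. As the WS220 chromosome lengths were not at hand, each chromosome was taken to end at the last base of any peak in either replicate list (100.2 Mb in all). Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and all random draws used a fixed seed.

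The tests were checked on simulated data of 1539 peaks. Unrelated lists were called as overlapping in 2 of 50 simulations, uniform lists as clustered in 0 of 50 and as concentrated in the domains on IV in 2 of 50 (200 shifts or placements each). Lists built to share 769 of their peaks, at slightly moved positions, were found to share 50.6%.

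Sites named in the text follow a rule fixed before the data were examined: the 25 combined peaks of highest rank, of which the first 10 are given with positions, and the 5 windows of 500 kb with the most peaks. The main tests, the domain windows on IV and the alternatives listed below were fixed at the same time. Tests of peak width and of window counts were not among them. The alternatives were the top peaks of each replicate alone, the 769 highest-ranked combined peaks, merging within 1 kb, reciprocal overlap of at least 50%, midpoints within 200 bp, other depths, and wider domain windows. Planned assignments of peaks to genes, gene lists, genomic features and sequence motifs were not made, because the gene table at hand is of assembly WBcel235 and not of WS220, and no genome sequence was used here. From that table only the number of genes of each class per chromosome was taken, for the closing section.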

Results

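Binding of GEI-11 to the genome of Caenorhabditis elegans embryos was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq). GEI-11, also called SNPC-4, is a Myb-domain protein and a subunit of the small nuclear RNA activating complex, which acts at snRNA, spliced-leader RNA and piRNA genes. The animals carried a transgene in which GEI-11 is fused to GFP and FLAG tags, and chromatin was precipitated with antibodies against GFP. The series holds 4 samples, namely 2 ChIP libraries and the 2 input DNA libraries made from the same kind of extract. Peaks were deposited as a list for each ChIP replicate and as 1 combined list, all on genome build WS220. No read counts accompany the lists, so the sequencing depth behind each peak is unknown. The labels number the replicates but do not say whether they were separate cultures, so agreement between them may reflect technical repeats only.

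The combined list held 1539 peaks, all on the 5 autosomes and X, that together covered 0.557% of the chromosomes. They are called binding sites, or sites, in what follows. Whether each reflects binding by GEI-11 itself was not tested. Each replicate list held 30000 peaks, covering 11.3% of the chromosomes in replicate 1 and 11.4% in replicate 2. Most combined peaks (1206, or 78.4%) were 400 bp wide, 285 were narrower and 48 were wider, up to 839 bp. Scores within the combined list ran from 1.73 to 3.24, and 856 peaks (55.6%) shared the highest value. The authors' peak number was therefore used to order tied peaks. All 48 wider peaks lay among the 769 highest-ranked combined peaks and 0 among the 770 others (two-sided Fisher's exact p = 1.61e-15). That test was not among those fixed beforehand. The boundary between these sets falls among peaks tied at the highest score, so it rests on the peak number. Narrower peaks were also mostly among the 769, 280 of 285, and the median width was 400 bp in both sets.

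The first-ranked binding site, among those tied at the highest score, lay on the left part of chromosome I, at position 2084678 to 2085273. It ranked 1 in the combined list and in both replicates. The next sites were at 8500269 to 8500751 on V, at 12250070 to 12250593 on III, at 4171883 to 4172524 on I and at 13463663 to 13464189 on I. Sites ranked 6 to 10 were at 15025626 to 15026141 and 5844513 to 5845123 on II, at 8228757 to 8229219 on V, at 14018185 to 14018628 on II and at 10989298 to 10989857 on III. All 25 top sites were autosomal, with 9 on II, 6 on I, 4 on IV, 4 on V and 2 on III. None of these 25 lay on X, which allows a share on X of up to 12% by a limit of 3 counts and up to 13.7% by the exact 95% interval, against 17.7% of the span (two-sided exact binomial p = 0.015, a test chosen after the values were seen). The 25 were 405 to 839 bp wide, and their lowest-placed members ranked 32 in replicate 1 and 27 in replicate 2. Of the 25, 22 were among the top 25 of both replicate lists.

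The first comparison asked how far the replicates found the same binding sites. Among the top 1539 peaks of each list, 60.1% of the replicate 1 peaks on the autosomes and X (911 of 1517, 95% exact interval 57.5 to 62.5%) were overlapped by at least 1 bp by a replicate 2 peak. The reverse share was 59.8% (908 of 1518). Circular shifts of the replicate 1 peaks within chromosomes gave 1.16% on average, and the observed share was 51.9 times that (one-sided permutation p = 0.0001, the smallest that 10000 shifts can give). The overlap was 91.9% for the top 100 peaks, 73.4% for the top 500 and 50.3% for the top 3000. Over all 30000 peaks it was 38.9% against 21.8% after shifting, 1.79 times the shifted value (permutation p = 0.001, the smallest that 1000 shifts can give).

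**Figure D1:**
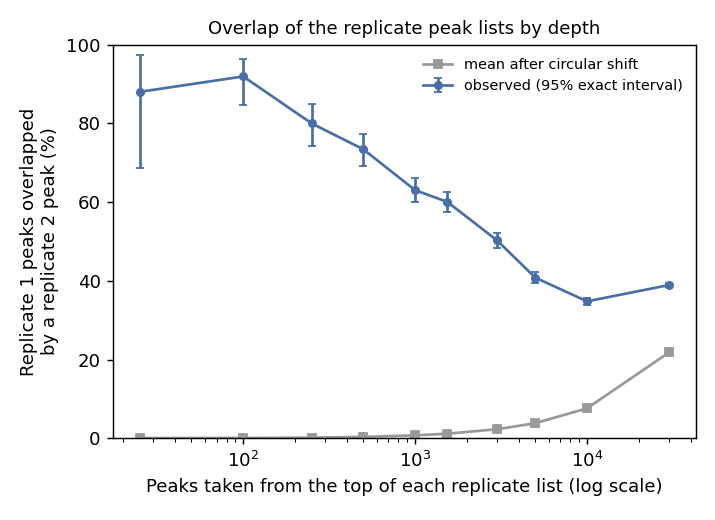
Percent of replicate 1 peaks on the autosomes and X overlapped by a replicate 2 peak (vertical axis) for increasing numbers of peaks taken from the top of each list (horizontal log axis), with 95% exact intervals, and the mean after circular shifts of replicate 1 (grey). The observed share is 88% at the top 25, 91.9% at the top 100, 34.8% at the top 10000 and 38.9% over all peaks, where shifting alone gives 21.8%.

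The replicates also ordered their highest-ranked sites alike. Across the 853 one-to-one matched peaks that lay in the top 1539 of both lists, the Spearman correlation of ranks was 0.74, and the median distance between matched midpoints was 21.5 bp. Across all 10529 matched pairs rho was 0.41, and the median distance was 89 bp. After shifting replicate 2 within chromosomes, 6002 pairs matched by chance on average over 20 shifts, with a mean rho of -0.00041. These correlations are across peaks, which are not independent replicates, and carry no p-value. The highest score was shared by 1154 peaks in replicate 1 and 681 in replicate 2. Ranks within these ties rest on the authors' peak number alone, and whether that number follows peak strength was not tested.

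**Figure D2:**
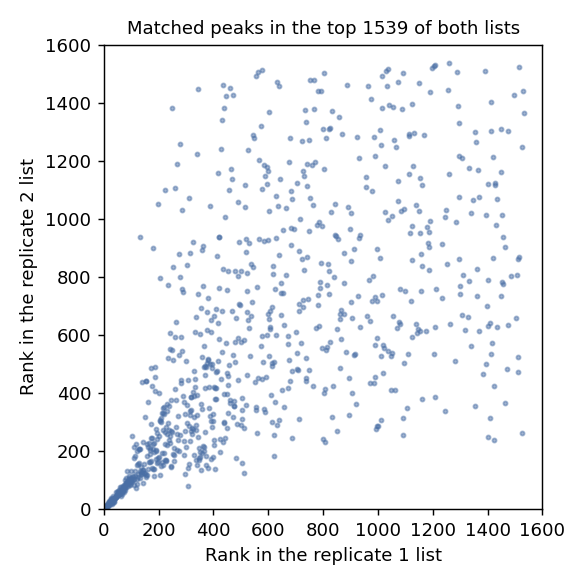
Rank in the replicate 1 list (horizontal axis) against rank in the replicate 2 list (vertical axis) for the 853 matched peaks in the top 1539 of both lists, 1 point per pair, rank 1 being the top of the list. Points lie close to the diagonal among the highest-ranked sites and spread out at lower ranks (rho = 0.74). Peaks tied at the highest score (1154 in replicate 1, 681 in replicate 2) are ordered by the authors' peak number.

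The second comparison asked what the combined list kept. Nearly all combined sites had a peak in each replicate list, with 99.6% overlapped in replicate 1 and 99.5% in replicate 2, against 21.2% for either list after shifting. Restricted to the top 1539 peaks, 77.6% of combined sites (1194) were overlapped in replicate 1 and 77.1% (1187) in replicate 2, and 58.4% (899) in both. For the 769 highest-ranked combined sites these shares were 96.2% and 95.4%, and for the other 770 they were 59.0% and 58.8%. In the other direction, 320 of the 1517 top peaks of replicate 1 on the autosomes and X and 326 of the 1518 of replicate 2 were absent from the combined list, of which 214 and 249 overlapped some peak of the other replicate's full list.

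The third comparison asked where in the genome the binding sites lay. X held more sites than its length gives and chromosome V fewer. X carried 338 of 1539 sites (22%, 95% exact interval 19.9 to 24.1%), against 17.7% of the span. This made 19.1 sites per Mb and 1.24 times the expected number (two-sided exact binomial, Benjamini-Hochberg adjusted p = 5.52e-05 over 6 chromosomes). V carried 236 sites (15.3%, 13.6 to 17.2%) on 20.9% of the span, 11.3 per Mb and 0.735 times the expected number (exact binomial, adjusted p = 2.27e-07). Chromosomes I to IV lay between 14.9 and 16.6 sites per Mb, with adjusted p of 0.379 to 0.972. The distribution over the 6 chromosomes differed from their lengths (chi-square 40.7, 5 degrees of freedom, p = 1.07e-07). The top 1539 peaks of replicate 1 alone placed 22.5% on X and 15.2% on V, and those of replicate 2 alone 21.2% and 15.5%. These tests treat sites as independent, which neighbouring sites are not.

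**Figure D3:**
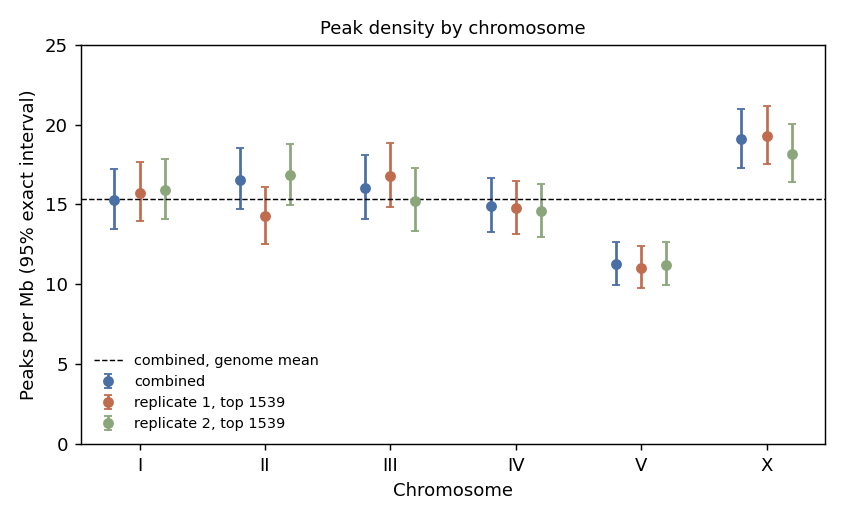
Peaks per Mb of chromosome (vertical axis, from 0) on each chromosome for the combined list and for the top 1539 peaks of each replicate, with 95% exact intervals from counting error only; the dashed line is the genome mean of the combined list. X lies above the line (19.1 per Mb combined) and V below it (11.3 per Mb combined) in all 3 sets.

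Sites on X were densest in its right part. The 5 windows of 500 kb with the most sites in the genome all lay on X, at 15.5 to 16 Mb (28 sites), at 14.5 to 15 Mb (25 sites) and at 14 to 14.5, 15 to 15.5 and 16 to 16.5 Mb (23 sites each). The mean over full windows was 7.68 sites. When the same number of sites was placed at random on each chromosome, the fullest window in the genome held 23 or more at a permutation p of 0.005 over 10000 draws, 25 or more at 0.0006 and 28 or more at 0.0002. The window at 14 to 14.5 Mb was less full in the single replicates, with 14 of the top peaks of replicate 1 and 16 of those of replicate 2. The stretch of X from 14 to 17 Mb, chosen after these values were seen, held 141 sites, 47 per Mb, against 13.4 per Mb in the rest of X and 14.6 per Mb on the autosomes. It held 43 per Mb of the top peaks of replicate 1 and 44.3 per Mb of those of replicate 2. The fullest run of this length on an autosome held 88 sites. The fullest in the genome held 95 at most in 10000 random placements (permutation p = 0.0001, the smallest they can give). Random placement, for the windows and for this run, treats sites as independent, which neighbouring sites are not, so these p-values may be too small. When the fullest 3 Mb of every chromosome was left out of both peaks and span, X held 18.5% of the remaining combined sites on 17.9% of the remaining span (exact binomial p = 0.603).

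Sites were sparse in the middle of X. Of all combined sites, 27.4% (421, 95% exact interval 25.1 to 29.7%) had their midpoint in the middle one of 3 equal parts of their chromosome, against an expected 33.3% (two-sided exact binomial p = 4.76e-07). On X this was 15.4% (52 of 338), and on the autosomes together 30.7% (369 of 1201, exact binomial p = 0.0577 against 33.3%). The autosomal share exceeded that of X by 15.3 percentage points (two-sided Fisher's exact p = 7.78e-09, a comparison chosen after the values were seen). Tests on these shares also treat sites as independent, which neighbouring sites are not. Among the 769 highest-ranked sites the shares were 7.69% on X and 32% on the autosomes. The right part of chromosomes held 42.8% of all sites, with 54.7% of those on X and 51.4% of those on II, where the window from 14.5 to 15 Mb held 21 sites, but 78 of 230 on I and 80 of 236 on V.

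**Figure D4:**
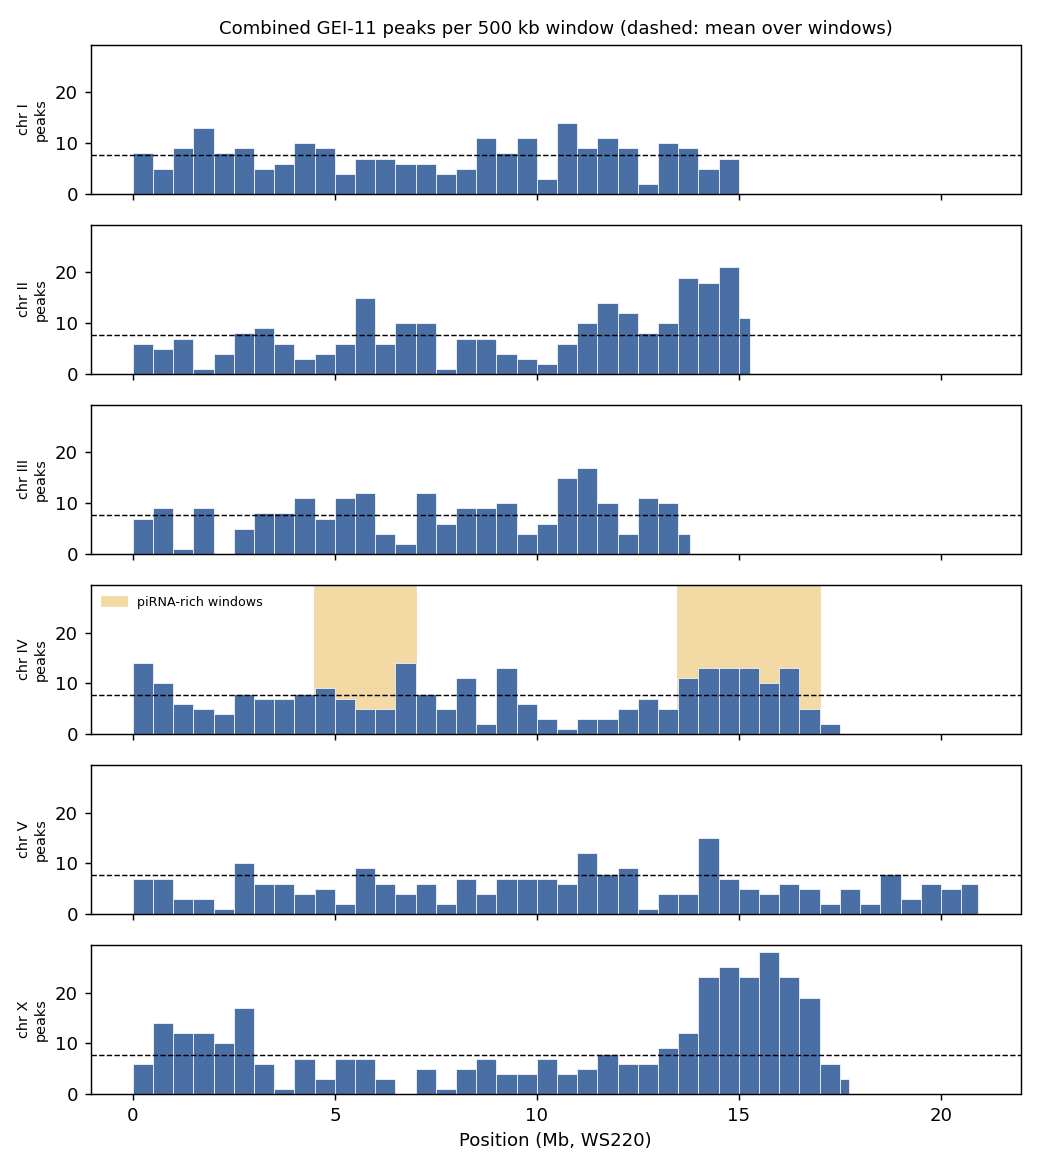
Number of combined peaks (vertical axis) in each 500 kb window along the chromosomes (horizontal axis, Mb on WS220), 1 panel per chromosome; the dashed line is the mean of 7.68 per full window and shading on IV marks the piRNA-rich windows. The fullest windows lie between 14 and 17 Mb on X, up to 28 peaks.

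Chromosome IV carries the 2 large domains in which most piRNA genes of the worm lie, and the fourth comparison asked whether sites were concentrated there. Windows fixed before the data were examined, at 4.5 to 7 and 13.5 to 17 Mb, held 118 of the 261 sites on IV, or 45.2% (95% exact interval 39.1 to 51.5%) on 34.3% of the span. Circular shifts on IV gave 34.4% on average with 95% of shifts between 22.2 and 44.8% (two-sided permutation p = 0.0396). Density was 16 per Mb in the left domain, 22.3 per Mb in the right domain and 12.4 per Mb elsewhere on IV. The call did not hold for the top peaks of replicate 1 alone (41.5%, permutation p = 0.145), for the 769 highest-ranked sites (47.2%, p = 0.0672), or with the windows widened by 500 kb on each side where the chromosome allowed (54% on 45.7% of the span, p = 0.378).

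Sites lay closer together than random placement gives. The median gap between neighbouring midpoints was 34.03 kb, against 44.3 kb for uniform placement of the same number per chromosome, with 95% of 10000 placements between 41.9 and 46.6 kb (two-sided permutation p = 0.0002, the smallest this test can give). Gaps under 5 kb numbered 256, against 116.4 on average and at most 149 in 1000 random placements, and gaps under 1 kb numbered 74, against 24.3 and at most 39. The 1539 entries form 1502 separate regions and include 7 repeated intervals. Some of the short gaps thus lie between overlapping or abutting entries, not between separate sites. With sites within 1 kb merged into 1439 regions, the median gap was 38.2 kb against 47.3 kb. Gaps under 5 kb then numbered 154, a count not set against random placement of the merged regions.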

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

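The tests in this part were chosen after the results were seen. Peaks on mitochondrial DNA, which were left out of the tests in the report, appeared in both replicate lists and nowhere in the combined list.

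Replicate 1 listed 29 mitochondrial peaks covering 9189 bp, and replicate 2 listed 26 covering 6776 bp. One explanation is that abundant mitochondrial DNA passed only because the replicate lists are permissive. The ranks argue against it, as the best mitochondrial peak ranked 58 in replicate 1 and 69 in replicate 2, and 22 and 21 of them lay in the top 1539. A second explanation is removal by a reproducibility filter on rank and overlap. Of the matched mitochondrial pairs, 13 had both members in the top 1539 and 0 are in the combined list. Among nuclear pairs of that kind 847 of 853 (99.3%) are. So are 744 of the 749 nuclear pairs whose worse rank lay in the range of the mitochondrial pairs. However, circular shifts of the mitochondrial peaks gave nearly as many pairs, 11.8 on average (one-sided permutation p = 0.29). The ranks of the 13 pairs had a Spearman rho of 0.093, against 0.74 for the 853 nuclear pairs. Their median midpoint distance was 60 bp, against 21.5 bp. The 13 may thus be chance pairs, which such a filter would remove, and this explanation stays open. A separate step that left out mitochondrial DNA, and whether the signal is binding or an imperfect correction for a very abundant template, stay open, since the files record no such step and the input reads were not analysed here.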

How the results depend on the processing

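The shares on X and V, the low pooled share in chromosome middles and the short median gap kept their direction. They did so, keeping their side of the 0.05 threshold, in each replicate alone, among the 769 highest-ranked sites and after 1 kb merging. Overlap between replicates kept both under its 4 other definitions (38.9 to 65.4%). The low middle share was carried mainly by X, as the pooled autosomes passed the threshold in no set (30.7% combined, 32.3 and 32.4% in replicates 1 and 2 alone, 32% among the 769 highest-ranked sites, 31.1% merged, exact binomial p = 0.0577 to 0.516). Single autosomes differed. V lay above the expected 33.3% in all of these sets, at 39.6% in replicate 2 alone (exact binomial p = 0.0448, not adjusted). II lay below 33.3% in all of them, at 26.9% combined (exact binomial p = 0.0326, not adjusted) and 27.1% merged (exact binomial p = 0.0494, not adjusted). Of 51 alternatives fixed before the data were examined, 39 left the result in place. These include the alternatives for chromosomes I to IV, where a result that was not called stayed so. The share of chromosome IV sites in the piRNA-rich windows, 45.2%, lost its call in replicate 1 alone (41.5 to 46.7% over the single replicates), among the 769 highest-ranked sites (47.2%) and with wider windows (54%); the cause was not tested. Chosen after seeing the data, leaving out the fullest 3 Mb of every chromosome ended the call for X, at 18.5% of sites on 17.9% of span (19.6 and 18% in replicates 1 and 2 alone, and 16.3%, below the span, among the 769 highest-ranked sites). Leaving out 14 to 17 Mb of X only, which lowers its share by construction, gave 14.1% on 15.1%, 15.3% in replicate 1, 13.6% in replicate 2 and 12% among the 769 highest-ranked sites, the last a called deficit (exact binomial p = 0.0246). The rank correlation of 0.41 became 0.74 in the top 1539 of both lists and 0.48 under reciprocal overlap. Reciprocal overlap lowered the share of combined sites found in the full replicate lists to 89.6 and 89.1%, and in their top 1539 to 67.6 and 66.7%; the 769 highest-ranked sites gave 100% in the full replicate 1 list and 96.2 and 95.4% in the top 1539. No paired analysis was possible because the input samples have no peak list of their own. Assignments to genes, features and motifs, and their alternatives, were not run. Read depth is unknown, so which peaks it limits cannot be said.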

Other observations

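X held 14 of the 100 highest-ranked combined sites (14%, 95% exact interval 7.87 to 22.4%), 24.5% of ranks 101 to 300 and 26% of ranks 301 to 600 (21.1 to 31.4%), then 21% of ranks 601 to 1000 and of the remaining 539. Sites up to rank 856 share one score and are ordered by the authors' peak number alone, and the differences between these ranges were not tested. The 769 highest-ranked sites and the other 770 had 22% and 21.9% of their members on X (two-sided Fisher's exact p = 1). The dense stretch of X from 14 to 17 Mb held 87 of the 769 highest-ranked sites, 29 per Mb, against 5.57 per Mb in the rest of X and 7.27 per Mb on the autosomes.

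For the excess on X and its dense stretch, the tests on weak peaks were chosen after the result was seen, while those on merging and on tRNA and protein-coding gene content were written before it. The share on X was 22.5 and 21.2% in the top 1539 peaks of replicates 1 and 2 (of those on the autosomes and X). In the weakest 10000 it was 19% and 18.2%, against 17.7% of the span. The difference was 3.56 percentage points in replicate 1 (95% interval 1.32 to 5.8) and 3.03 in replicate 2 (0.841 to 5.22), with peaks treated as independent. With 14 to 17 Mb of X left out, X held 15.3 and 13.6% of the top 1539. It then held 15.8 and 15.6% of the weakest 10000, on 15.1% of the remaining span. The difference thus rests on the dense stretch, and it cannot exclude a background that favours X at every peak strength. The density of the weakest 10000 peaks in the stretch was 1.23 (1.1 to 1.38) and 0.997 (0.879 to 1.13) times that in the rest of X. For the top 1539 it was 2.97 (2.37 to 3.71) and 3.45 (2.74 to 4.33) times. These values cannot decide on higher copy number or background over the stretch. Either could raise scores there and move peaks out of the weakest ranks, and the input reads were not analysed here. Several peaks called at one site do not account for the excess on X, as X held 22.8% of sites after merging. Open chromatin that draws many tagged factors stays open, since no other factor was analysed here.

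A hypothesis was that the excess on X may follow the gene content of the chromosomes, tested over 6 chromosomes with 7 gene classes counted per Mb, using the WBcel235 gene table for chromosome membership only; predictions were written beforehand for protein-coding and tRNA genes, and the other classes were exploratory. Protein-coding genes went the other way (Pearson r = -0.77, exact permutation p = 0.0917, adjusted p = 0.214; Spearman rho = -0.43, p = 0.419, adjusted p = 0.587; r = 0.83 without V and X), with X the poorest in them at 154.1 per Mb. For tRNA genes, of which X holds 276 of 612 (45.1%), r was 0.71 (exact permutation p = 0.21, adjusted p = 0.367) and rho 0.66 (p = 0.175, adjusted p = 0.408). Here r was 0.44 without X and -0.25 without V and X. The pair of chromosomes left out in each class has the lowest and the highest density of its genes, so leaving them out also narrows the range. The tRNA relation leans on that pair and cannot be told apart from chance with 6 points. For snRNA genes, known targets of the complex, r was -0.78 (exact permutation p = 0.0792, adjusted p = 0.214) and rho -0.89 (p = 0.0333, adjusted p = 0.233), with r of -0.97 without IV and X, and for piRNA genes r was -0.12 (exact permutation p = 0.558, adjusted p = 0.651) and rho -0.43 (p = 0.419, adjusted p = 0.587), with r of -0.23 without III and IV. Among the 7 classes miRNA genes gave the highest r, 0.87 (exact permutation p = 0.0292, adjusted p = 0.204), with rho 0.77 (p = 0.103, adjusted p = 0.36) and r of 0.22 without V and X. For snoRNA genes r was -0.066 (0.80 without X), and for genes classed as ncRNA it was 0.58 (-0.47 without X). Leaving out X alone gave r of 0.74 for miRNA, -0.55 for protein-coding, -0.58 for snRNA and 0.025 for piRNA genes. None of the 7 classes passed the adjustment.

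The concentration of chromosome IV sites in the piRNA-rich windows may instead be a rise towards chromosome ends that other chromosomes share, a test chosen after the result was seen. Windows at the same relative positions on the other 5 chromosomes held 41.8% of their sites (39.1 to 44.5%), against 45.2% on IV (39.1 to 51.5%), and the difference was not called (two-sided Fisher's exact p = 0.336). The share was 50.6% on X and 48.6% on II, but 29.7% on V and 33% on I, and without X the other 4 autosomes held 38.6% (35.5 to 41.8%). The pooled value thus rests in part on X, and the explanation stays open. A specific concentration at piRNA genes was not tested, as no gene positions on WS220 were used here.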
